A study of Mus musculus with 6 samples.

How the data were processed

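RNA-seq was available for 4 groups of mouse embryonic fibroblasts (MEF, cells grown from the connective tissue of mouse embryos, here on a C57BL/6 background): wild-type and Dot1L null cells, each untreated or exposed to sodium arsenite, an inorganic arsenic salt, for 24 h. Dot1L is the methyltransferase of lysine 79 of histone H3. Each group held 1 library. The labels name the exposure as low; the treatment protocol lists 5 and 10 µM beside 0 µM and does not say which of them was sequenced. A further 2 libraries, H3K27ac ChIP-seq of wild-type cells with and without arsenite, were not analysed here.

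Per the labels' protocols, ribosomal RNA was removed with a Ribo-zero kit and strand-specific libraries were made by the dUTP method and sequenced as paired ends, whereas the molecule label reads polyA RNA. The labels do not settle which selection was used. TopHat, HTSeq, Bowtie and deepTools are named in the submitters' processing notes together with the mouse build mm10, without versions or roles. The authors deposited their expression values as RPKM (reads scaled to gene length and to library depth) in a table of 37224 Ensembl gene IDs and 4 columns; the gene annotation behind it and the strand setting of the counting are not given in the sources used here. A symbol was found for 35449 of the IDs, and 1775 had none. Gene positions are from the RefSeq annotation of GRCm38, the assembly also known as mm10. No genome sequence was used, so exons and untranslated regions are not described.

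The RPKM values move in whole-read steps, which made it possible to recover depth. For each library, the most frequent value of the inverse of RPKM times length, the value a gene with 1 read would give, was found over small RNA genes, whose annotated span is their transcript length. It was taken as the number of reads by which the authors divided. The shortest gene length that turned all of a gene's values into whole reads, within a relative tolerance of 1e-12, was then taken as its length. Such a length was found for 21616 of the 21617 genes above 0 in any library, Ttn being the exception. That a length was found does not show that it is right. Of 501 small RNA genes with reads and an annotated span, 348 had a recovered length equal to the span. In 389 it was the span or a whole fraction of it. The remaining lengths were neither, and the annotation behind the deposited values is not given. A recovered length can be too short by a whole factor, and genes under 200 bases were left out of every calculation on length. Recovered reads were used for counting intervals, for gene length and for thinning, never for a count model.

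Differences were computed as log2((RPKM + 1)/(RPKM + 1)), a scale that understates the difference of genes with low values, over the 12588 genes with an RPKM of at least 1 in any of the 4 libraries, with no further scaling. A gene was counted as higher or lower at a 2-fold difference on that scale. The difference of the arsenite effects is the log2 fold in Dot1L null cells minus that in wild-type cells. With 1 library per group there is no replicate check: no p-value, standard error or test across genes was computed, and each comparison sets a library against a library. Intervals are exact conditional (Clopper-Pearson) 95% intervals of the ratio of reads. They cover counting error only, and leave out variation between cultures and between libraries. They also treat each read as an independent molecule. Reads without molecular identifiers are not, so the intervals can be too narrow even for counting error. Where a gene had 0 reads in a library, the fold is a bound against a floor of 3 reads in that library.

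The rule for the genes named was set before the data were examined, as were the gene lists, the thresholds and the alternatives, except those described as added later. Symbols typical of predicted genes, pseudogenes, microRNAs, small nucleolar RNAs and spliceosomal RNAs (Gm with digits, Rik at the end, Mir, Snor, Rnu, n-R5 or LOC at the start, or -ps) and IDs without a symbol are left out; small RNAs with other symbols, such as Rn7sk, are kept. The rule takes the 10 highest and 10 lowest genes for arsenite in wild type and for untreated null against wild type, the 10 genes with the largest differences in each direction shared by both genotypes, the 5 most positive and 5 most negative differences of the arsenite effects, up to 4 members of each list with the largest differences in a comparison, and Dot1l, Ep300, Crebbp, Hmox1, Mt1, Mt2, Cdkn1a and Cdkn2a. Some genes that the rule selects are not reported here as single genes, though they remain in their lists. There were 29 gene lists, covering stress pathways, cell cycle, matrix, inflammation, metabolism, ribosome, proteasome, chromatin and control groups, and 9 lists of cell type markers. For a list with at least 3 members past the filter, the median log2 fold is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. This describes these libraries and is not a test of the treatment or the genotype. A list is said to lie outside the matched range where its percentile is below 2.5 or above 97.5.

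Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at an RPKM of 5, centring on the median of all genes, scaling to the 75th percentile, leaving out predicted and small RNA genes by the same symbols, thresholds of 1.5-fold and 4-fold, a counting interval that excludes 1, and random lists without matching. Removal of a lowess trend of log2 fold on log2 length (span 0.3), which also centres all genes near 0, and random lists matched on both expression and length (10 by 10 bins) were added after the data were seen. The slope on length was fitted to genes with a mean RPKM of at least 5 over the 4 libraries; this gene set replaced an earlier one, with an RPKM of at least 5 in every library, after the first slopes had been seen.

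Several steps were tested on simulated data before use. The recovery of depth was not among them, because the simulation was given the depths. The simulated libraries differed only by depth, counting error and the changes put in, with no other variation between libraries and no length trend. The rates below are therefore not error rates of the real comparisons. In 12588 genes drawn from the reads of the wild-type control, 97.0% of genes with reads in every library had their length recovered exactly. The true lengths of the simulation were those recovered from the real data. This share therefore does not show that the lengths of the real genes are right. Past the 2-fold threshold were 91.3% of genes raised by 1.5 on the log2 scale, 77.3% of those lowered by 1.5, 95.2% of those lowered by 3, and 0.483% of unchanged genes, and 95.4% of the counting intervals of unchanged genes held 1. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.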

Results

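Gene expression was measured by RNA-seq in wild-type and Dot1L null mouse embryonic fibroblasts, untreated or after 24 h of low-dose sodium arsenite, to describe the transcriptional response to arsenic across the genome. The series title concerns the histone acetyltransferase p300 and the acetylation of lysine 27 of histone H3, and the 2 libraries of that histone mark were not analysed here. Each of the 4 RNA groups held 1 library, so every difference is between libraries and has no replicate check. Depth, recovered from the deposited RPKM values, was 62972880 reads in the wild-type control, 10833103 with arsenite, 64699847 in the null control and 11879632 in the null with arsenite. The controls were thus 5.81 and 5.45 times deeper than the arsenite libraries. Genes above 0 numbered 19323, 15700, 18613 and 15313 in the same order. Controls thinned at random to the arsenite depth had 15962 genes above 0 in wild type and 15708 in the null, so depth goes with most of the drop. The 100 genes with most reads took 16.5% of the reads in the wild-type control and 34.6% with arsenite, against 20.2% and 41.3% in the null.

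Dot1l (ENSMUSG00000061589, chromosome 10, 80755101 to 80795461 in GRCm38) was lower in the libraries labelled Dot1L null, though not absent. Its RPKM was 30.4 in the wild-type control and 9.59 in the null control, 3.17-fold lower (95% counting interval 3.07 to 3.26). With arsenite it was 5.71 and 1.24, 4.61-fold lower (3.79 to 5.63). The table gives totals per gene, so a deleted part of the gene cannot be seen in it. Xist, the RNA of the inactive X chromosome, had RPKM values of 26.7, 3.86, 80.6 and 5.86 in the order above, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 4 libraries. Of the marker lists, 9 of 11 fibroblast genes passed the filter. Among markers of other cell types, 4 of 12 macrophage and leukocyte genes, 4 of 9 neural and glial genes, 4 of 9 cartilage and bone genes, 2 of 8 epithelial, 2 of 9 skeletal muscle, 2 of 7 adipocyte, 1 of 8 endothelial and none of 7 pluripotent and germ cell genes passed.

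**Figure D1:**
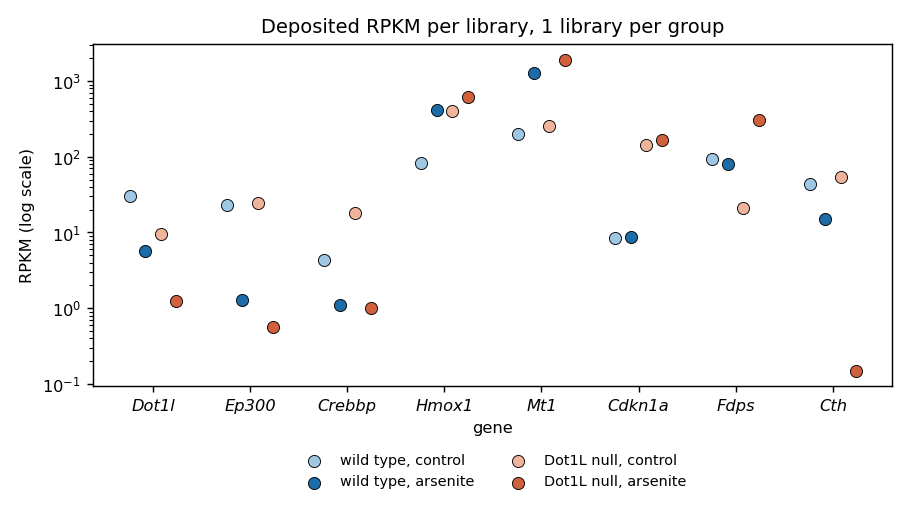
Deposited RPKM (log axis) of 8 genes in the 4 libraries, 1 point per library. Ep300 is at 23.1 and 24.2 in the 2 controls and at 1.29 and 0.558 with arsenite, and Fdps is at 21.0 in the null control and 310.4 in the null with arsenite.

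Arsenite was first compared with control in wild-type cells, a contrast that cannot separate the treatment from other differences between the 2 libraries. Genes of the antioxidant response were higher with arsenite, while genes of extracellular matrix, cholesterol synthesis, inflammation and the immediate early response were lower. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, had an RPKM of 82.4 in the control and 416 with arsenite, 5.05-fold higher (4.92 to 5.19). The metal-binding metallothioneins Mt1 and Mt2 were 6.21-fold (6.01 to 6.42) and 4.94-fold (4.81 to 5.08) higher. Ep300 (ENSMUSG00000055024, chromosome 15, 81586209 to 81652077 in GRCm38), which encodes p300, had 12753 reads in the control and 122 with arsenite. At RPKM values of 23.1 and 1.29 it was 18.0-fold lower (15.05 to 21.7). Its paralog Crebbp was 3.97-fold lower (3.21 to 4.97). Both are long genes: with the trend on gene length described below removed, the log2 fold of Ep300 was −2.02 in place of −3.40 and that of Crebbp −0.04 in place of −1.35. Cdkn1a, an inhibitor of cyclin-dependent kinases, stood at 8.56 and 8.84, and Cdkn2a at 118 and 222.

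In all, 1609 of 12588 genes were at least 2-fold higher and 4495 at least 2-fold lower, so 26.4% of the genes past the threshold were higher. The median of all genes was −0.56 on the log2 scale. The split depended on scaling: 52.8% were higher after centring on that median, 43.3% after scaling to the 75th percentile and 50.7% after the length trend was removed. Differences also followed gene length. The median was 1.01 for genes of 500 to under 1000 bases and −1.54 for genes of at least 12000 bases, a slope of −0.92 per doubling of length over 7252 genes. List medians are therefore given with their distance from the median of all genes where this matters, and with a percentile among lists matched on length as well where that moves them into the matched range.

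**Figure D2:**
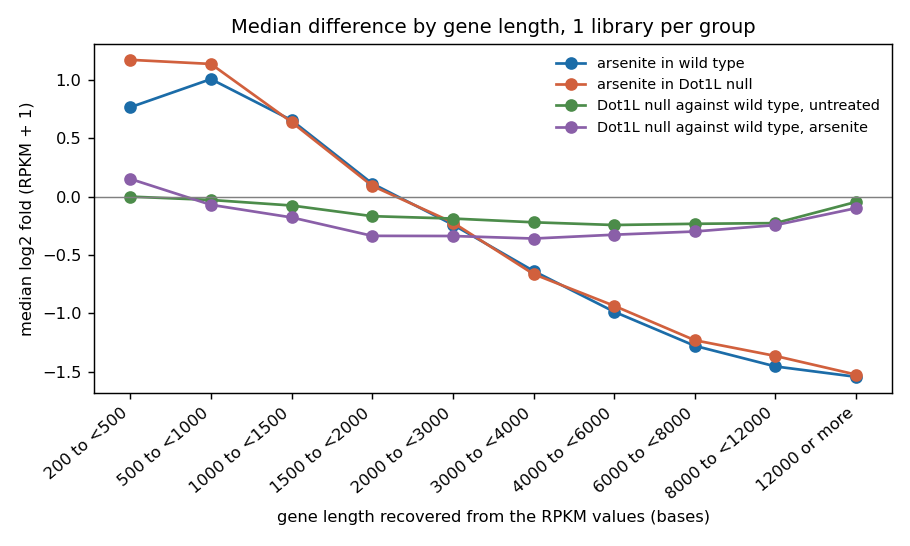
Median log2 fold of genes grouped by recovered length in bases, for the 4 comparisons, 1 library per group. Both arsenite comparisons run from above 0 in short genes to −1.54 in wild type and −1.52 in the null at 12000 bases or more, while the genotype comparisons have slopes of −0.05 and −0.07 per doubling.

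Of 27 NRF2 targets, the genes of the antioxidant response, 15 were higher and 3 lower (median log2 fold 1.28, which is 1.84 above the median of all genes, percentile 99.98). They included Blvrb (7.28 to 128 RPKM), Gsta4 (6.95 to 108), Nqo1 (14.4 to 132) and Taldo1 (34.9 to 228). Of 9 RNAs without a poly(A) tail, 7 were higher (median 2.87, percentile 100), among them Rpph1, Rn7sk and Rmrp, and 2 were lower. The labels leave the RNA selection unsettled, and a selection that differed between libraries could by itself set these RNAs apart. Of 17 interferon response genes, 5 were higher and 5 lower (median 0.32, percentile 99.84). With a filter at an RPKM of 5 that median was −0.17. Replication-dependent histones had a median of 0.45 (percentile 99.80), with 5 of 17 higher and 1 lower. Among lists matched on length too their percentile was 46.3, and their median was −0.46 with the length trend removed.

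Extracellular matrix genes were lower in 19 of 24 cases (median −2.55, 1.99 below the median of all genes, percentile 0). With the length trend removed 17 were lower and 1 higher (median −1.33). Thbs1, which encodes thrombospondin 1, had an RPKM of 458 in the control and 10.7 with arsenite, Col12a1 96.6 and 1.55, Fn1 565 and 30.7, and Fbn1 27.7 and 1.19. Of 22 cholesterol synthesis genes, 17 were lower and 1 higher (median −2.07, percentile 0), with Srebf2, a transcription factor of the pathway, at 84.1 and 10.0. Without the length trend 15 were lower and 1 higher (median −1.13). NF-kB targets and cytokines were lower in 17 of 23 cases (median −1.74, percentile 0.02), including Vcam1 and Cxcl10, with none higher. Immediate early genes were lower in 14 of 18 cases (median −1.69, percentile 0.01), including Klf4, Jun and Egr2. Of 23 ATF4 and CHOP targets, genes of the integrated stress response, 12 were lower and 1 higher (median −1.10, percentile 0), with Atf3 at 46.5 and 3.07. Histone acetyltransferases were lower in 10 of 14 cases and higher in none (median −1.89, percentile 0.04), but with the length trend removed 2 were lower and 1 higher (median −0.56). After Ep300 the lowest were Kat6a (23.1 to 2.81 RPKM), Ncoa2 (7.64 to 0.483) and Taf1 (15.6 to 2.42). Their median length was 7418 bases, and the percentile was 0.60 among lists matched on length as well. Smooth muscle and YAP-SRF targets had a median of −0.73 (percentile 0.61, and 7.06 with length matched).

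Ribosomal protein genes were higher in 32 of 35 cases (median 1.64) and proteasome genes in 20 of 28 (median 1.39), with percentiles of 93.3 and 95.9, inside the matched range. With length matched as well these became 98.5 and 99.9. Heat shock genes (median 0.27, 6 of 18 higher, 3 lower), mitochondrially encoded genes (1.49, 7 of 10 higher) and histone deacetylases (−0.63, 6 of 16 lower) also lay inside the matched range without length. So did DOT1L partners (−1.30, 9 of 13 lower), matrix metalloproteinases and serpins (−0.98, 7 of 14 lower), p53 targets (−0.99, 9 of 18 lower, 1 higher) and DNA repair genes (−0.61, 6 of 20 lower, 2 higher). With the length trend removed, the medians of p53 targets, deacetylases and DNA repair genes were above 0. DOT1L partners then had 3 of 13 lower (median −0.63) and heat shock genes 9 of 18 higher and 1 lower (0.78). Mitochondrially encoded genes then had 3 of 10 higher and 1 lower (0.75), and their percentile was 65.5 with length matched. Also inside the matched range were mitosis, glycolysis and hypoxia, metal response, endoplasmic reticulum chaperones, DNA replication, autophagy and lysosome, Hox and imprinted genes. Their medians lay between −0.47 and −0.02 and were above 0 after centring on the median of all genes. Fibroblast markers were lower in 5 of 9 cases and higher in 1 (median −1.51, percentile 0.40), with Dcn at 60.7 and 3.85 RPKM. Neural and glial markers had a median of −1.70 (percentile 1.07), with Sox2 at 15.8 and 3.19. Macrophage and leukocyte markers had a median of 0.61 (percentile 98.1, and 65.6 with length matched), and none of the 4 was past 2-fold.

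Among single genes that have a symbol and that the naming rule keeps, here and in the rankings below, the highest were Rpph1, Rn7sk, Lrrc17, mt-Tp, Rps27rt, Rmrp, Rpl37rt, S100a11, Pet100 and Usmg5. Lrrc17 had 5 reads in the control and 969 with arsenite (RPKM 0.0363 and 40.9). S100a11, which encodes a calcium-binding protein, went from an RPKM of 183 in the control to 3454 with arsenite. Rps27rt and Rpl37rt resemble ribosomal protein genes, and their reads could be shared with those near-identical genes, so their values are uncertain. The lowest were Thbs1, Col12a1, Klf4, Cdh11, Styx, Dag1, Hif1a, Irf2bpl, Ipo7 and Fn1. Thbs1 was 43.0-fold lower (39.9 to 46.4). Klf4, a transcription factor, was 62.4-fold lower (43.9 to 91.9). Styx had 807 reads in the control and 0 with arsenite, which makes it at least 46.3-fold lower.

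Arsenite against control in Dot1L null cells gave 1908 genes at least 2-fold higher and 4666 lower, with 29.0% of those past the threshold higher and a median of all genes of −0.53. The share higher was 49.6% after median centring, 45.9% after 75th percentile scaling and 48.8% without the length trend, and the slope on length was −0.94 per doubling. ATF4 and CHOP targets were lower in 21 of 23 cases (median −2.62, percentile 0), with Atf3 at 80.3 in the control and 1.19 with arsenite, Slc7a5, an amino acid transporter, at 289 and 18.0, and Trib3 at 96.2 and 5.98. Histone acetyltransferases were lower in 11 of 14 cases (median −2.37, percentile 0.04, and 0.09 with length matched), and in 7 with the length trend removed (median −1.01). Ep300 was 43.3-fold lower (33.5 to 57.1), from 24.2 to 0.558 RPKM, and Crebbp 18.2-fold lower (14.7 to 22.6). Their log2 folds were −2.67 and −1.95 without the length trend. Mt1 and Mt2 were 7.46-fold (7.26 to 7.67) and 9.60-fold (9.26 to 9.96) higher, and Hmox1 1.52-fold (1.498 to 1.55) higher. Cholesterol synthesis genes were higher in 8 of 22 cases and lower in 2 (median 0.30, percentile 99.1). Fdps, an enzyme of the pathway, was 14.8-fold higher (14.0 to 15.6), and Ebp went from 6.23 to 47.0 RPKM.

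Extracellular matrix genes in the null had a median of −1.48 (15 of 24 lower, 3 higher, percentile 0.03), which moved to percentile 15.9 when length was matched too. With the length trend removed 10 were lower and 7 higher (median −0.20). Replication-dependent histones were higher in 9 of 17 cases (median 1.28, percentile 100, and 93.2 with length matched), but in 1, with 2 lower, once the length trend was removed (median 0.13). RNAs without a poly(A) tail were higher in 6 of 9 cases and lower in 2 (median 2.71, percentile 100). NRF2 targets were split, with 11 higher and 9 lower (median 0.61, percentile 94.9). Gstm1 (31.2 to 332 RPKM) was among the higher members and Slc7a11 (10.7 to 0.269) among the lower. Immediate early genes (median −0.60, 7 of 18 lower, percentile 35.1) and NF-kB targets and cytokines (−0.65, 9 of 23 lower, 5 higher, percentile 19.2) lay inside the matched range. So did ribosomal proteins (1.36, 29 of 35 higher, percentile 89.2) and proteasome genes (0.43, 11 of 28 higher, 2 lower, percentile 28.5). Macrophage and leukocyte markers had a median of 0.62 (percentile 97.53, and 61.0 with length matched), with Cd68 at 2.02 and 5.56 RPKM.

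**Figure D3:**
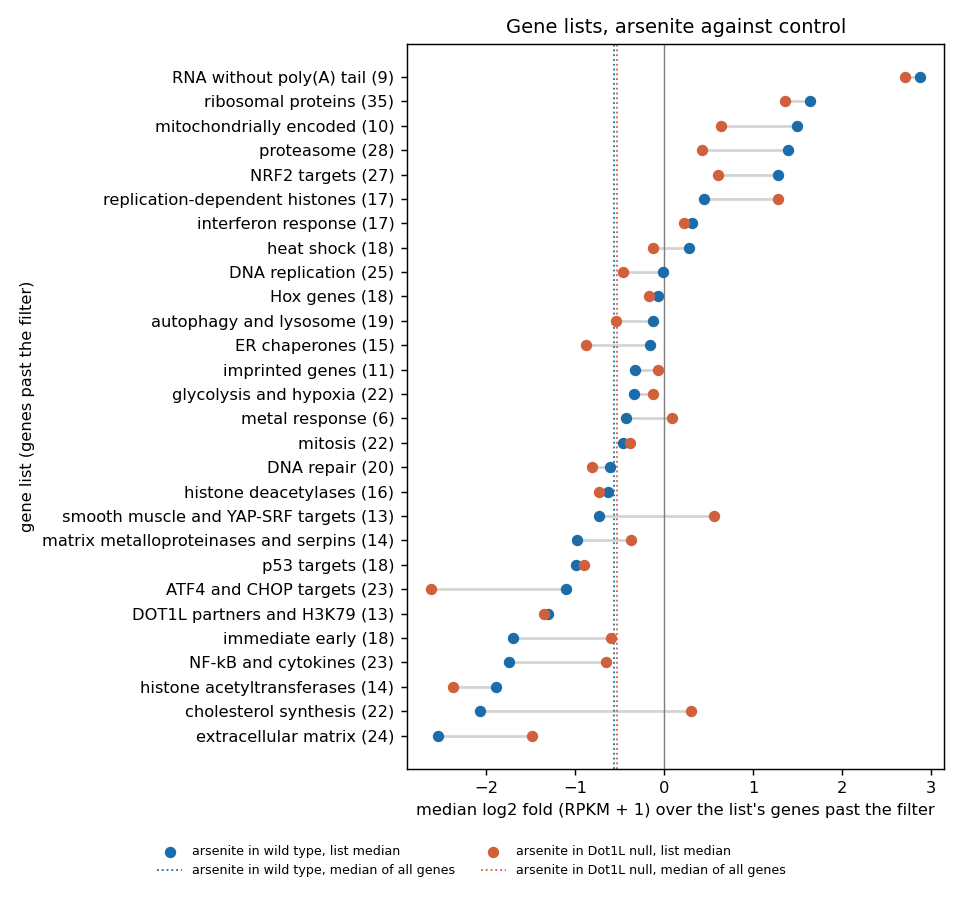
Median log2 fold (RPKM + 1) of 28 gene lists for arsenite against control in wild-type and Dot1L null cells, 1 library per group; dotted lines mark the medians of all genes, −0.56 and −0.53. Cholesterol synthesis is at −2.07 in wild type and 0.30 in the null, and histone acetyltransferases are at −1.89 and −2.37.

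Across genotypes, 1058 genes were higher and 3307 lower with arsenite in both, and 45 were past 2-fold in opposite ways. The excess of lower genes depended on scaling: 1888 were higher and 1730 lower in both after median centring, and 1218 and 1254 without the length trend. The 2 comparisons share no library. Independent lists of these sizes would share 244 higher and 1666 lower genes. Shuffling within expression bins gave averages of 377, 1874 and 1052 for higher, lower and opposite. Neither baseline holds gene length fixed, so the length trend that both comparisons show could by itself raise the overlap. Across genes, which are not independent replicates, the log2 folds had a Pearson correlation of 0.79 and a Spearman correlation of 0.77, or 0.72 and 0.70 once the length trend was removed. Of the genes with a symbol that the rule keeps, those higher in both were led by Rn7sk, Rps27rt, Rpl37rt, Rpph1, S100a11, Pet100, Rmrp, mt-Nd6, S100a13 and Vaultrc5. S100a13 went from 12.7 to 187 RPKM in wild type and from 8.86 to 369 in the null. Genes lower in both were led by Klf4, Thbs1, Ipo7, Fn1, Dag1, Hif1a, Grem1, Zfp445, Tnks and Krt80. Hif1a, the oxygen-regulated subunit of the hypoxia-inducible factor, went from 48.7 to 1.57 RPKM in wild type and from 60.3 to 2.64 in the null. Grem1, an antagonist of bone morphogenetic proteins, went from 100.4 to 5.23 and from 133 to 4.24.

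The difference of the arsenite effects, null minus wild type, was at least 1 on the log2 scale in 1524 genes and at most −1 in 1610. It was not tested against replicate error. Each of its libraries also enters the other comparisons, so it is not separate evidence from them. Cholesterol synthesis genes stood out with 21 of 22 more positive in the null (median of the differences 2.34, percentile 100), among them Fdps (4.03), Mvd (3.66) and Cyp51 (3.28). NF-kB targets and cytokines were more positive in 17 of 23 cases (1.26, percentile 100), with Ccl5 at 2.91 and Ccl7 at 2.55. For this list the wild-type control is shared with arsenite in wild type (−1.74) and with the untreated genotype comparison (−1.37). Between the 2 arsenite libraries its median was 0.001, with 4 of 23 higher in the null and 2 lower. Extracellular matrix genes were also more positive (12 of 24, 2 more negative, median 0.99, percentile 100), led by the collagen VI genes Col6a2 (3.49) and Col6a1 (3.41). Smooth muscle and YAP-SRF targets (8 of 13, median 1.11, percentile 100), with Acta2 at 3.62, and immediate early genes (9 of 18, 3 more negative, median 0.87, percentile 100), with Egr1 at 3.30, lay on the same side. Matrix metalloproteinases and serpins had a median of 0.92 (percentile 99.98). ATF4 and CHOP targets were more negative in 14 of 23 cases (median −1.55, percentile 0), led by Psph (−3.65) and Asns (−2.26). NRF2 targets were more negative in 15 of 27 (−1.05, percentile 0.01), led by Txnrd1 (−2.08) and Gsr (−2.07). Proteasome genes had a median of −0.78 (percentile 1.35) and DNA replication genes one of −0.66 (percentile 0.69). Fibroblast markers (5 of 9, median 1.06, percentile 99.9) and neural and glial markers (3 of 4, median 1.41, percentile 99.8) were more positive. Replication-dependent histones had a median of 0.71 (percentile 98.8, and 80.3 with length matched), with 5 of 17 more positive and 12 past neither bound.

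Among the most positive genes were Guca1a, Fdps, Izumo4 and Tmem86a, and the 5 most negative were Cox6a2, mt-Tq, Nid1, Thbd and Cth. Guca1a had 1 and 3 reads in the wild-type libraries, a ratio of 17.4 with a counting interval from 1.40 to 916. Cth, which encodes the cysteine-producing enzyme cystathionine gamma-lyase, was 2.96-fold lower with arsenite in wild type (2.67 to 3.30). In the null it went from 7981 reads to 4 and was 366-fold lower (143 to 1345). Nid1 and Thbd had 8 and 4 reads in wild type with arsenite, and their negative differences rest on the null, where Nid1 went from 87.9 to 2.48 RPKM and Thbd from 112 to 3.78.

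Untreated Dot1L null cells were next set against untreated wild-type cells. This contrast cannot separate the genotype from other differences between the 2 libraries or the cells they came from. Targets of p53 and Hox genes were higher in the null, and genes of mitosis, cholesterol synthesis and inflammation were lower. So were 12 of 25 DNA replication genes, or 6 with the length trend removed and all genes centred near 0. Cdkn1a, a p53 target, was 16.7-fold higher (15.7 to 17.7), at 8.56 RPKM in wild type and 143 in the null. Cdkn2a, another inhibitor of the cell cycle, was 2.94-fold lower (2.82 to 3.07). Hmox1 was 4.92-fold higher (4.82 to 5.02). In all, 812 genes were at least 2-fold higher and 1852 lower (30.5% of those past the threshold higher, median of all genes −0.17). The share higher was 43.9% after median centring, 39.2% after 75th percentile scaling and 45.9% without the length trend.

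Of 18 p53 targets, 11 were higher and 2 lower (median 1.51, percentile 100), with Ccng1 at 12.6 and 153 RPKM and Eda2r at 1.40 and 25.01. Hox genes, which pattern the body axis, were higher in 10 of 18 cases and lower in none (median 1.25, percentile 100). Hoxb9 stood at 3.23 and 37.7 RPKM, and Hoxa10 at 0.145 and 4.10. Mitosis genes were lower in 20 of 22 cases (median −1.87, percentile 0), with Birc5 at 35.3 and 4.55 and Ccna2, cyclin A2, at 72.8 and 10.7. DNA replication genes were lower in 12 of 25 (median −0.995, percentile 0), with Mcm6 at 89.5 and 23.9. With the length trend removed, which also centres all genes near 0, 6 were lower (median −0.83). The percentile was 0 with length matched too. Cholesterol synthesis genes were lower in 19 of 22 (median −1.36, percentile 0). NF-kB targets and cytokines were lower in 14 of 23 and higher in 5 (median −1.37, percentile 0). The 2 members furthest from 0, Il1rl1 (7.43 to 111) and Cxcl1 (3.53 to 49.4), were higher. The medians of 3 lists were shifted upward, though most of their members stayed within 2-fold. They were NRF2 targets (median 0.53, 8 of 27 higher, 1 lower, percentile 99.99) and endoplasmic reticulum chaperones (0.60, 2 of 15 higher, percentile 99.9). The third was genes of autophagy and the lysosome (0.52, 5 of 19 higher, 1 lower, percentile 99.9). Hspa5, the chaperone BiP, stood at 244 and 585 RPKM. Imprinted genes had a median of 0.41 (percentile 99.6), with Igf2 at 1.77 and 43.3, and a median of −0.07 with a filter at an RPKM of 5. Extracellular matrix genes went both ways, 7 higher and 9 lower (median −0.45, percentile 0.09). The medians of replication-dependent histones (−0.55, 4 of 17 lower, percentile 0.28) and immediate early genes (−0.41, 7 of 18 lower, percentile 2.45, and 3.77 with length matched) were shifted downward. So was that of smooth muscle and YAP-SRF targets (−0.41, 4 of 13 lower, 2 higher, percentile 2.35, and 5.13 with length matched).

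Markers of other lineages also differed between the untreated libraries. Neural and glial markers had a median of −1.37 (percentile 0.07), with Sox2 at 15.8 RPKM in wild type and 4.08 in the null. Cartilage and bone markers had a median of −1.93 (percentile 0.06), with Spp1 at 1058 and 67.0 but Sox9 at 2.80 and 25.7. Fibroblast markers had a median of −0.55 (percentile 2.23, and 2.62 with length matched). Some lists had too few members for a percentile. Of 2 epithelial genes past the filter, 1 was at least 2-fold lower and 1 higher, Krt19, at 0.608 and 7.57. The muscle gene Tnnt2 stood at 14.2 and 1.41, the adipocyte gene Fabp4 at 1.42 and 1.77 and the endothelial gene Cdh5 at 0.0677 and 1.501. The highest single genes were Cd34, Efemp1, Thbd, Plp2, Ctsz, Nid1, Fbln2, Ass1, Maoa and Osr1. Cd34, a surface protein of progenitor and vascular cells, was 168-fold higher (149 to 191), at 1.53 and 258 RPKM. The lowest were Msln, Mmp3, Eya1, Rps3a3, Sulf1, Pdgfb, Rab26os, Colec12, Pde8a and Lmcd1. Msln, which encodes mesothelin, was 78.9-fold lower (66.5 to 94.3). Rps3a3 resembles a ribosomal protein gene, and its reads could be shared with it.

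Null against wild type under arsenite gave 1102 genes higher and 2130 lower (34.1% of those past the threshold higher, median of all genes −0.28). The share higher was 57.1% after median centring, 47.7% after 75th percentile scaling and 58.2% without the length trend. Of the genes past 2-fold, 368 were higher and 720 lower in the null under both treatments and 51 went opposite ways, against 71.1 and 313 for independent lists and a shuffled average of 297 opposite. The correlation across genes was 0.52 (Pearson) and 0.42 (Spearman). Targets of p53 were again higher, 11 of 18 with none lower (median 1.34, percentile 100), with Cdkn1a 18.99-fold higher (16.5 to 21.9), and so were Hox genes, 12 of 18 (median 1.58, percentile 100). Mitosis genes were lower in 21 of 22 cases (median −1.70, percentile 0) and DNA replication genes in 22 of 25 (−1.65, percentile 0), with Pcna, the sliding clamp of replication, at 150.2 RPKM in wild type and 18.0 in the null. DNA repair genes had a median of −0.87 (percentile 0.47), and ATF4 and CHOP targets one of −1.003 (percentile 0.02). Heat shock genes had a median of −0.66 (percentile 1.70).

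Some groups stood on opposite sides of 0 under the 2 treatments. Cholesterol synthesis genes were higher in the null with arsenite in 11 of 22 cases (median 1.06, percentile 100), with Fdps at 81.2 and 310.4 RPKM. Extracellular matrix genes were higher in 9 of 24 and lower in 3 (0.56, percentile 100), and matrix metalloproteinases and serpins in 5 of 14 (0.65, percentile 99.95), with Mmp2 at 3.68 and 129. NRF2 targets were lower in 10 of 27 and higher in 2 (−0.59, percentile 1.39, and 2.04 with length matched), with Nqo1 at 132 and 14.7. With the length trend removed, which also centres all genes near 0, 4 were lower and 4 higher (−0.23). The slope on length was only −0.07 per doubling in this comparison. The medians of smooth muscle and YAP-SRF targets (0.47, 5 of 13 higher, 2 lower, percentile 99.1) and fibroblast markers (0.52, 3 of 9 higher, percentile 98.8) lay above 0. Immediate early genes had a median of 0.11 (percentile 97.9), but 3 of 18 were higher and 4 lower. Replication-dependent histones had a median of 0.47 (percentile 99.84, and 85.1 with length matched), which was −0.50 with a filter at an RPKM of 5. Proteasome genes had a median of −0.46 (percentile 2.38, and 4.30 with length matched). Ep300 stood at 1.29 RPKM in wild type and 0.558 in the null.

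**Figure D4:**
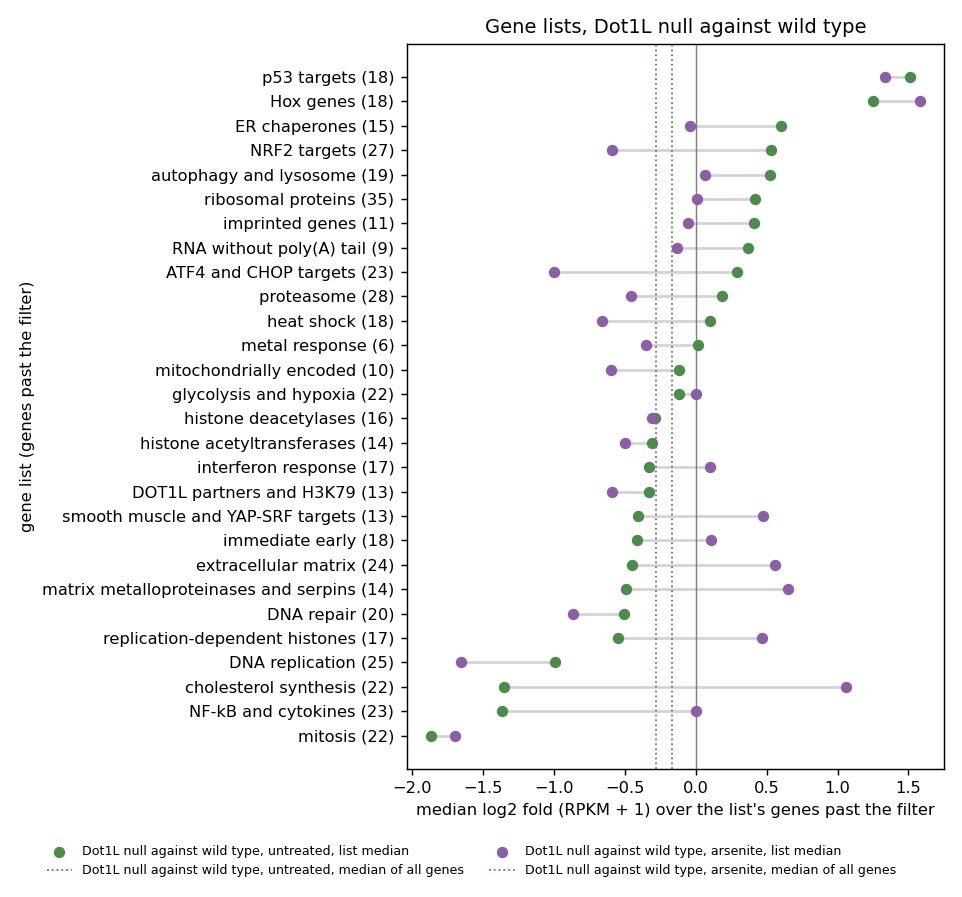
Median log2 fold (RPKM + 1) of 28 gene lists for Dot1L null against wild type, untreated and under arsenite, 1 library per group; dotted lines mark the medians of all genes, −0.17 and −0.28. The p53 targets are at 1.51 and 1.34, mitosis at −1.87 and −1.70, and cholesterol synthesis at −1.36 and 1.06.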

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

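With 1 library per group none of the differences below was tested. They are results in which the same contrast pointed opposite ways in the 2 genotypes or the 2 treatments: single genes past 2-fold in each direction, or gene lists outside the matched range on opposite sides. Only genes that the naming rule selects outside the lists were searched; of all genes, 45 were past 2-fold in opposite ways for arsenite and 51 for genotype. The same 4 libraries enter both views, so the treatments and the genotypes are not separate evidence.

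For arsenite in the 2 genotypes, Cox6a2, a cytochrome c oxidase subunit (ENSMUSG00000030785, chromosome 7, 128205435 to 128206366 in GRCm38), had log2 folds of 3.17 in wild type and −2.21 in the null, a difference of −5.37. By reads it was 11.6-fold higher (95% counting interval 9.34 to 14.5) and 5.74-fold lower (3.86 to 8.93). The mitochondrial tRNA gene mt-Tq had 2.69 and −2.16, a difference of −4.86, but rests on 7 and 12 reads in wild type and 16 and 0 in the null. Against a floor of 3 reads its null fold is not distinguishable from 1. Cholesterol synthesis had medians of −2.07 and 0.30, and the median of the differences was 2.34.

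For genotype under the 2 treatments, mt-Tp had log2 folds of 1.01 untreated and −2.72 with arsenite (difference −3.73), on 8 to 52 reads per library. Fdps had −2.11 and 1.92 (4.03), Izumo4 −1.83 and 2.05 (3.89) and Cox6a2 2.27 and −3.10 (−5.37). Among lists, the medians were −1.36 and 1.06 for cholesterol synthesis (median of the differences 2.34), 0.53 and −0.59 for NRF2 targets (−1.05), −0.55 and 0.47 for replication-dependent histones (0.71; the median under arsenite was −0.50 with a filter at an RPKM of 5), −0.45 and 0.56 for extracellular matrix (0.99), −0.41 and 0.47 for smooth muscle and YAP-SRF targets (1.11), −0.41 and 0.11 for immediate early genes (0.87), and −0.55 and 0.52 for fibroblast markers (1.06). With length matched as well, some of these fall inside the matched range: histones under arsenite (percentile 85.1), and, untreated, smooth muscle and YAP-SRF targets (5.13), immediate early genes (3.77) and fibroblast markers (2.62).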

How the results depend on the processing

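No paired analysis was possible because each group held 1 library, and for the same reason no replicate could be left out. Removal of the length trend and matching on length were chosen after the data were seen. All 12 counts of genes stayed within 1.5 times the reported value with a pseudocount of 0.5 and with a filter at an RPKM of 5. They also did so without predicted and small RNA genes, and where the counting interval had to exclude 1. With no filter they stayed so too, but except for the difference of the arsenite effects this was fixed in advance. With a pseudocount of 1, a gene under an RPKM of 1 in every library cannot reach 2-fold. The following counts moved further, and unless stated the cause was not tested. With a pseudocount of 0.1, 1244 genes were higher in the untreated null, 3596 were lower in the null under arsenite and 2612 differences of the arsenite effects were negative. Median centring, which moves every gene by the same amount, gave 2721 higher and 2437 lower for arsenite in wild type, 2948 and 2997 in the null, 1888 and 1730 in both, and 1213 lower in the null under arsenite. Scaling to the 75th percentile gave 2416 higher in wild type, 2977 in the null and 1757 in both. A 1.5-fold threshold, which counts more genes by construction, gave 1785 and 3514 for the untreated null, 1917 and 4209 for the null under arsenite, 2880 and 3276 for the difference and 1661 higher in both. A 4-fold threshold gave 517 and 1305, 657 and 1900, 207 and 361, 303 and 276, and 265 and 191 for the 4 comparisons and the difference in the order reported, and 322 and 885 in both. Without the length trend, 1871 genes were lower in wild type, 2555 in the null, 1254 in both, and 1089 in the null under arsenite. Of the lists outside the matched range, the sign of the median turned for replication-dependent histones (arsenite in wild type, −0.46 without the length trend; null against wild type under arsenite, −0.50 at an RPKM of 5), interferon genes (wild type, −0.17 at an RPKM of 5), macrophage markers (wild type, −0.13 at an RPKM of 5 and −0.11 without the length trend; null, −0.15 without it) and imprinted genes (untreated null, −0.072 at an RPKM of 5). Beyond these, 291 list medians over all alternatives moved by more than the spread of random lists, 89 of them by median centring and 78 by removal of the length trend, some across 0 among lists inside the matched range. Of the values of the genes named, 403 moved by more than counting error and 429 did not; removal of the length trend moved 94 and left 66. The arsenite libraries limit the precision: 3 reads of a gene of 2000 bases are an RPKM of 0.138 there in wild type and 0.0238 in the control.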

Other observations

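The tests of library differences and of reads placed on near-identical copies were chosen after the results were seen, as was the matching of the immediate early list on length.

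Rn7sk, a small nuclear RNA that restrains transcription elongation, had an RPKM of 3.60 in the wild-type control and 186 with arsenite, and 3.88 and 169.6 in the null. It has no poly(A) tail, so its values depend on an RNA selection that the labels leave unsettled. Neat1, the scaffold of nuclear paraspeckles, stood at 128 in untreated wild type and 16.1 in the untreated null, and Malat1 at 113 and 186. An unnamed gene of 71 bases, ENSMUSG00000093126, singled out after its values were seen, had 10 reads in the wild-type control and 21821 with arsenite, and 4 and 1930 in the null.

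Arsenite folds decreased with gene length in both genotypes, by −0.92 per doubling at the shallower. Random loss of reads did not give this slope. A control thinned to the arsenite depth, set against itself in full, had a slope of at most 0.00178. In it 38 genes in wild type and 34 in the null passed 2-fold. Thinning keeps each gene's expected RPKM whatever its length, so a slope near 0 was largely set in advance. The test covers fewer reads alone and does not decide on other effects of lower depth. Differences in RNA quality or library making that came with the arsenite libraries cannot be told apart from the treatment, because each treated group is a single library (slope −0.924 at the shallower). A loss of short-lived mRNAs, which would add to the trend and not account for it, is a candidate only. No half-lives were used, and the immediate early list stood in for such mRNAs. With the trend removed, immediate early genes had medians of −1.75 in wild type and −0.707 in the null, past the bound of −0.5 set beforehand. The null value lay at percentile 12.8 among lists matched on expression and length, so there it is not unusual for such genes.

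Of 19 pseudogenes of ribosomal proteins with at least 10 reads in each control, 16 in wild type and 15 in the null differed more upward with arsenite than their parent genes (median difference 1.47 and 2.85). Their shorter length (median 475 against 1434 bases) may contribute: with the length trend removed the medians were 0.91 and 2.24, above the 0.5 that length alone would leave, but not above 1 in both. A different share of reads placed on near-identical copies stays open too. It would leave the genotypes alike within a treatment, and the median was −0.31 between untreated libraries but 1.32 between arsenite libraries, against the 1.47 at the smaller of the arsenite comparisons. No biological explanation was tested.

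Histone acetyltransferase genes, which are long, were lower with arsenite in both genotypes. Length as the whole cause is argued against by matching alone. Among random lists matched on expression and length the medians lay at percentile 0.60 at the higher of the 2 genotypes. With the trend removed they were −0.56 in wild type and −1.01 in the null, and the wild-type value does not add to this. In wild type DOT1L partners, with a median length of 7451 bases, had −0.63 with the trend removed but percentile 56.4 with length matched. Without the trend, a step that also centres all genes near 0, 2 of 14 genes in wild type (from 10) and 7 in the null (from 11) were 2-fold lower, and 1 in wild type was higher; how much of this is length was not separated. A response to arsenite remains a hypothesis, since library differences, which coincide with treatment, were not excluded.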
